A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

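RNA of Saccharomyces cerevisiae, isolated by the submitters with hot phenol and labelled with biotin, was measured on 15 Affymetrix yeast arrays. The labels gave genotype, agent and time, and placed 3 arrays in each of 5 groups, which were wild type untreated (0 min) and wild type, yap1, yap8 and y1y8 with arsenate (60 min). The dose of 2 mM comes from the design text of the series, which describes growth in arsenate until exponential phase and not an exposure of 60 min. That text also describes double mutant cells carrying empty plasmids or plasmids with YAP1 or YAP8, but the labels do not say which group carried which plasmid, and no group was assigned from it. It names another array type than the probe set identifiers of the files belong to, and the identifiers were followed. A file name of treated wild-type replicate 2 carries the letters RH, which the labels do not explain, and the array was kept.

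The deposited file of each array held a linear intensity (Signal) for each of 10928 probe sets with a detection call of present, marginal or absent. Per the file headers and values these intensities were not scaled between arrays by the authors. The submitters' processing notes name Partek without a version, and the summary method is not given in the sources used here. The series matrix held the same intensities, with a largest difference of 0. A deposited workbook held the authors' own comparison tables with model-based intensities, means and signed linear fold changes (a score that is negative where the second group was lower) with their bounds, for 3 comparisons. The tool behind them is not given in the sources used here, and its 18 call columns were not used.

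Probe sets were assigned to genes from the platform annotation and, where it gave no gene, from the workbook. Of the probe sets, 213 were controls, 5638 matched 1 yeast gene (5498 by the platform annotation and 140 by the workbook), 1746 belonged to another species, 1 matched several genes and 3330 had no gene name. Of 3688 probe sets named in both sources 3684 had the same locus. For 48 genes with several probe sets, the one with the highest mean log2 value over all arrays was used, which left 5588 genes. No genome build is named in the files, so genes are placed only by their neighbours in a gene table of assembly R64.

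Intensities were quantile normalized over all probe sets and all arrays, values under 1 were set to 1, and log2 was taken. Median intensity over all probe sets ran from 46.2 to 101.6 per array before this step and the highest from 10786.6 to 12565.3. Exactly equal deposited intensities were found at 120 to 186 of the 10928 probe sets in each pair of replicates and at 113 to 207 in pairs of arrays from different groups, and log2 differences between replicates had an SD of 0.191 to 0.374. For arrays the number of arrays limits the precision.

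Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on a group-means model with all 15 arrays, two-sided, Benjamini-Hochberg over 5588 genes, threshold 0.05). There were 8 comparisons, which were arsenate in wild type, each mutant against treated wild type, the 3 comparisons between mutants, and the departure of y1y8 from the sum of the single losses. A gene called absent on all arrays of a group was given a bound in place of its fitted fold. The bound takes each absent array at its own value or at the lowest value among probe sets called present on it, whichever is higher. That lowest value is not a measured detection limit, and other processing can give a smaller fold. The limit for dim probe sets, a log2 value of 2.79, is the 95th percentile of the probe sets of another species.

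Gene lists were tested with camera (preset correlation of 0.01, 25 of 27 lists with at least 5 measured genes, Benjamini-Hochberg within a comparison), and again with an estimated correlation and with fry, which tests whether a list moves on balance and does not compare it with other genes. A list is said to pass where it passed camera, and its adjusted p is from camera unless fry is named. With an estimated correlation 5 of the 27 list calls made in the first 4 comparisons held, namely Yap1 targets in wild type, yap1 and y1y8, and sulfate and zinc genes in wild type. Overlaps of calls were set beside the product of both counts over the genes tested and beside 100 simulated sets of groups without change that shared the same arrays.

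The genes named were fixed by a rule. It took the regulator and arsenic genes in every comparison, the 8 largest rises and 8 largest falls of the first 4 comparisons (4 and 4 of the others) among genes with a standard symbol past the threshold whose groups did not overlap, up to 3 members of each list and the largest against its direction, and URA3 and LEU2. With 3 arrays against 3, groups without difference fail to overlap in 1 of 10 splits. YDL218W, YOR387C, YDR042C, YBR090C, YOR186W, YKR005C, KEL2, HBN1, MET17, FET3, FTR1, FIT3 and the members named in the closing section were added after their values were seen. The groups, comparisons, 27 lists, naming rule and all alternatives except 1 were fixed before the data were examined. A further 3 lists, on the cell cycle and hypoxia, were added after the data were seen and appear in the closing section alone.

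The alternatives were the series matrix, median centring, quantile normalization over yeast probe sets alone, 16 added before log2, dim probe sets left out, all probe sets that were not controls or of another species, only the groups of a comparison, replicate number as a block, eBayes with trend and robust prior, array weights, a test against a fold of 1.2, camera with an estimated correlation, and each array left out in turn. Gene names from the platform annotation alone were added after the data were seen. The alternative with all probe sets held the 3330 without a gene name, and some of these may belong to another species. The pipeline was tested on simulated data, where changes of log2 0.5, 1, 2 and 4 were recovered for 31, 46, 50 and 50 of 50 genes each. Of 198 simulated calls 21 (10.6%) fell on unchanged genes, and 8 of 189 without the quantile step. In the simulated list test 2 of 100 lists without a shift had p under 0.05. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.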

Results

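The arrays measured RNA of budding yeast exposed to arsenate, the pentavalent form of arsenic (AsV), at 2 mM as the series design text gives it. That text describes growth in arsenate until exponential phase, while the labels give 60 min, so whether this dose applies to the 60 min exposure is not settled by the sources. The 15 arrays fell into 5 groups of 3: wild-type cells without treatment at 0 min, wild-type cells after 60 min of arsenate, and 3 mutants after 60 min of arsenate. The mutants were yap1, which lacks the stress regulator Yap1, yap8, which lacks the arsenic regulator Yap8 (gene ARR1), and y1y8, which lacks both. Median signal over the probe sets of yeast genes ran from 548.1 to 933.8 per array, against 1.8 to 2.9 for probe sets of another species on the same array. Between 98.4% and 99.3% of the yeast probe sets were called present on each array. Replicates of a group correlated at 0.9802 to 0.9946 across genes, which are not independent replicates, and the number of arrays limits the precision. Whether the 3 replicates of a group were separate cultures is not stated, so each p below measures the spread between arrays only. All values are log2 changes ± SE from limma over 5588 genes with n = 3 arrays per group, and adjusted p is given over all genes unless another family is named.

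The probe sets of the deleted regulators were examined first. YAP1 had a mean log2 signal of 11.67 (SD 0.16) in arsenate-treated wild-type cells and 11.70 (SD 0.16) in yap8, but 9.21 (SD 0.21) in yap1 and 9.20 (SD 0.12) in y1y8. Its signal was 5.52-fold lower in yap1 than in wild type (adjusted p = 1.5e-08) and 5.56-fold lower in y1y8 (adjusted p = 1.22e-08), so it did not reach background. ARR1 was at 11.23 (SD 0.13) in treated wild type and 10.99 (SD 0.12) in yap1, and was called absent on all 3 arrays of yap8 and of y1y8. By the bound used here its signal was 391-fold lower in yap8 and 423-fold lower in y1y8 than in wild type. Adding 16 before log2 gave smaller log2 changes of -6.86 and -6.93. The submitters' deposited fold for yap8 was -163.01, with bounds of -103.06 and -382.44. The size of this fall thus depends on the processing. The genotypes on the labels and these signals went the same way on every array of the 4 treated groups.

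**Figure D1:**
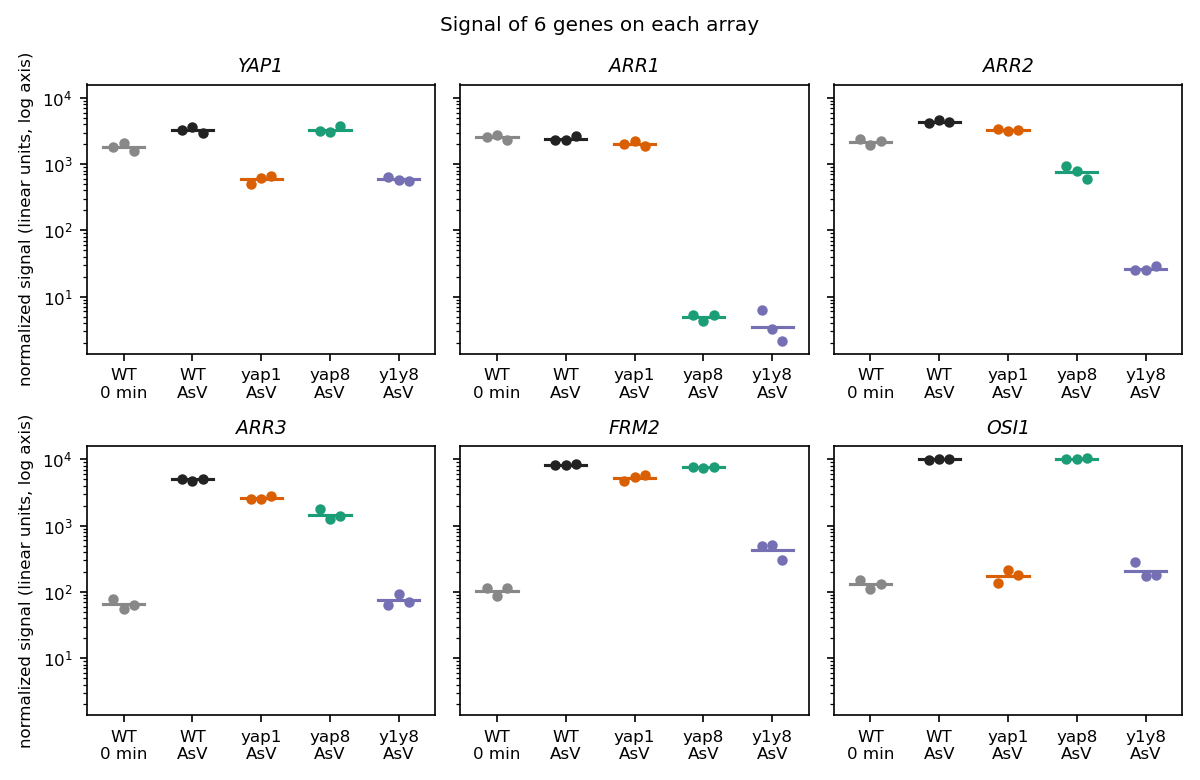
Normalized signal (linear units on a log axis) of 6 genes on each of the 15 arrays, by group. Points are arrays and lines are means of the log values. ARR1 signal was low in yap8 and y1y8, and ARR2, ARR3 and FRM2 were lowest among the treated groups in y1y8.

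The first comparison asked what 60 min of arsenate did to wild-type cells, and time and arsenate changed together because no untreated group was kept for 60 min. Relative to other genes, arsenate-treated cells held far more RNA for sulfate uptake, arsenite export and thiol defence. SUL1, a sulfate permease, was 101-fold higher (6.66 ± 0.09, adjusted p = 7.33e-15), and ARR3, the exporter of arsenite, was 76.6-fold higher (6.26 ± 0.16, adjusted p = 1.02e-12). ARR2, the arsenate reductase encoded beside ARR3, rose by 1.01 ± 0.13 (adjusted p = 7.8e-06). YAP1 itself rose by 0.85 ± 0.13 (adjusted p = 4.48e-05), while ARR1 differed by -0.08 ± 0.27 (adjusted p = 0.798). Other large rises were FRM2, a nitroreductase-like protein (80.8-fold), OSI1 (77.6-fold), the membrane heat shock protein gene HSP30 (52.8-fold), the old yellow enzyme gene OYE3 (46.7-fold), the sulfiredoxin gene SRX1 (46.1-fold) and the transporter gene SEO1 (38.8-fold). YDL218W, a gene without a standard symbol, rose 58.5-fold.

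The largest falls in treated wild-type cells among genes with a standard symbol were VEL1 (68.2-fold), INA1 (28.8-fold), the cell wall protein gene TOS6 (27.5-fold) and HO, the mating-type switching endonuclease (26.5-fold). The adenine deaminase gene AAH1 fell 24.7-fold, the CTP synthase gene URA7 22.8-fold, FAR1, an inhibitor of the cell cycle kinase, 22.2-fold, and the phospholipase gene PLB2 21-fold. YOR387C, a gene without a standard symbol, fell 69.2-fold. For each of these rises and falls the 3 arrays of one group lay beyond the 3 of the other. The naming rule required this of the largest changes among genes with a standard symbol, so it lends them no further support.

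Of 36 measured Yap1 oxidative and thiol stress targets, 35 rose, none fell and the mean log2 change was 2.66 (camera adjusted p = 3.98e-12). The count was the same adjusted over the list alone. Sulfate assimilation and methionine genes moved by the same mean, with 31 of 36 up and 2 down (adjusted p = 6.67e-11), and the counts were again the same adjusted over the list alone. Among them JLP1, a sulfonate dioxygenase, rose by 5.05 beside SUL1 and SEO1, while MET13, a methylenetetrahydrofolate reductase, fell by 0.71. MET17, a methionine synthesis gene, had a mean log2 signal of 2.01 in untreated and 2.84 in treated wild type. These values lie near the limit for dim probe sets of 2.79, and whether the gene was intact in these cells was not tested. Both lists held with an estimated correlation, at adjusted p = 0.000487 and adjusted p = 0.0194.

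Of 24 glutathione and glutaredoxin genes, 19 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.000299, but adjusted p = 0.057 with an estimated correlation). The glutathione transferases GTT2 and GTO1 rose by 5.02 and 4.06, and the glutaredoxin GRX4 fell by 1.67. Heat shock chaperones rose in 26 of 30 cases and fell in 3, with the same counts adjusted over the list alone (adjusted p = 6.65e-06, but adjusted p = 0.057 with an estimated correlation), led after HSP30 by the Hsp70 gene SSA3 (4.23) and BTN2 (4.21). SSB1, the ribosome-bound Hsp70, fell by 1.08. Proteasome genes rose in 38 of 39 cases and fell in 1, with a smaller mean of 0.80, with the same counts adjusted over the list alone (adjusted p = 2.18e-09, but adjusted p = 0.0903 with an estimated correlation), among them the core subunit PRE8 and the lid subunit RPN6 (1.25 each).

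Of 40 general stress and carbohydrate reserve genes, 30 rose and 3 fell (30 and 4 adjusted over the list alone), with TMA10 up by 3.70 and the glycogen synthase gene GSY1 down at -2.34 (adjusted p = 0.000841, but adjusted p = 0.621 with an estimated correlation). Cell wall integrity genes rose in 12 of 18 cases and fell in 3, with the same counts adjusted over the list alone (adjusted p = 0.0157, adjusted p = 0.202 with an estimated correlation). The list call was also lost with median centring. Its examples were the wall protein gene PIR3 (2.08) and the kinase gene SLT2 (1.67).

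Ribosomal protein and ribosome biogenesis genes were lower. Of 129 cytosolic ribosomal protein genes 127 fell and 1, RPL15B, rose (0.26, a call that ended in 3 of the alternatives), and the mean log2 change was -2.06 (adjusted p = 5.98e-31, but adjusted p = 0.0632 with an estimated correlation). RPL9A fell by 3.72 and RPS10B by 3.48. All 86 ribosome biogenesis genes fell, with a mean of -1.79 (adjusted p = 1.75e-16, but adjusted p = 0.306 with an estimated correlation), among them the RNA helicase DBP2 (-3.72) and RPA190, the largest subunit of RNA polymerase I (-2.89). Both sets of counts were the same adjusted over the list alone.

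Ergosterol biosynthesis genes fell in 21 of 25 cases and rose in 1 (adjusted p = 2.01e-06, adjusted p = 0.108 with an estimated correlation). Examples were ERG3 (-3.16), ERG25 (-2.33) and HMG1, an HMG-CoA reductase (-2.14), against ERG9 (0.42), whose call was lost with median centring. Of 15 zinc deficiency genes 14 fell and none rose (adjusted p = 5.99e-05, adjusted p = 0.0361 with an estimated correlation), among them IZH1 (-2.94) and ZPS1 (-2.93). All 9 core histone genes fell (adjusted p = 0.0015, adjusted p = 0.116 with an estimated correlation), with HTB2 at -2.68. The counts of these 3 lists were the same adjusted over the list alone.

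Of 31 iron uptake and mobilisation genes 20 rose and 6 fell (adjusted p = 0.0264, adjusted p = 0.183 with an estimated correlation), a call that also ended without wild-type untreated replicate 2. The haem oxygenase gene HMX1 rose by 3.12 and TIS11, which acts in the decay of iron-related mRNA, by 2.52, and FIT1, a wall mannoprotein for siderophore retention, fell by 1.53. Mean log2 signal of the iron uptake genes FET3 and FTR1 was 10.71 and 10.43 in untreated but 9.48 and 9.58 in treated wild type. That of FIT3 was 10 and 10.38. The list of iron, iron-sulfur and haem protein genes went the other way from the uptake list, with 20 of 30 down and 7 up (adjusted p = 0.0165, adjusted p = 0.057 with an estimated correlation). The members that rose included the catalase gene CTA1 (2.80) and the iron-responsive regulator YAP5 (2.91). Both sets of counts were the same adjusted over the list alone.

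The remaining lists did not pass camera with quantile normalization. With fry, adjusted p was 1.07e-05 for Gcn4 targets, 5.41e-07 for DNA damage, 4.77e-06 for sporulation and 7.93e-10 for hexose transport. It was 0.00405 for phosphate starvation, 0.00459 for multidrug resistance and 0.00237 for copper homeostasis. Respiratory chain, MATa-specific, glycolysis and plasmid genes did not pass fry. Fry does not compare a list with other genes, and 4536 of 5588 genes differed here. Gcn4 amino acid biosynthesis genes had 24 of 42 up and 10 down (adjusted p = 0.101), and DNA damage response genes 9 of 15 up and 2 down (adjusted p = 0.101), with the photolyase gene PHR1 up by 2.40 and the ribonucleotide reductase gene RNR1 at -4.07. Sporulation genes had 14 of 22 up and 5 down (adjusted p = 0.207, but adjusted p = 0.0355 with median centring), hexose transport genes 3 of 14 up and 6 down (adjusted p = 0.293), and respiratory chain genes 5 of 38 up and 11 down (adjusted p = 0.448, but adjusted p = 0.0106 and a mean of -0.31 with median centring). MATa-specific genes had 1 of 6 up and 3 down (adjusted p = 0.63), and phosphate starvation genes 9 of 23 up and 4 down (8 and 4 adjusted over the list alone, adjusted p = 0.648). For glycolysis the counts were 5 of 16 up and 2 down (0 and 2 adjusted over the list alone, adjusted p = 0.872), with a mean of -0.05 and a median of 0.05. Hexose transport had 2 up and 6 down adjusted over the list alone. For multidrug resistance 9 of 22 were up and 9 down, for copper homeostasis 5 of 10 each way, with a mean of 0.05 and a median of -0.10, and for plasmid and marker genes 2 of 6 each way (adjusted p = 0.983 for each). The 4 measured MATalpha-specific genes all fell, too few for a set test. Where no second count is given, the counts were the same adjusted over the list alone.

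In total 4536 of 5588 genes differed between treated and untreated wild-type cells, 2343 higher and 2193 lower, and 959 and 992 of them by at least 2-fold. The median change of all genes was 0.03, and -0.03 after median centring. Both settings put the arrays on a common level, which holds this median near 0 and favours a near-even split. Changes in every comparison are thus relative to the other genes, and a shift of all RNA together would not show. Median centring called 4519 genes, of which 4340 were also among the 4536, and 12 of these 4340 had the other direction.

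**Figure D2:**
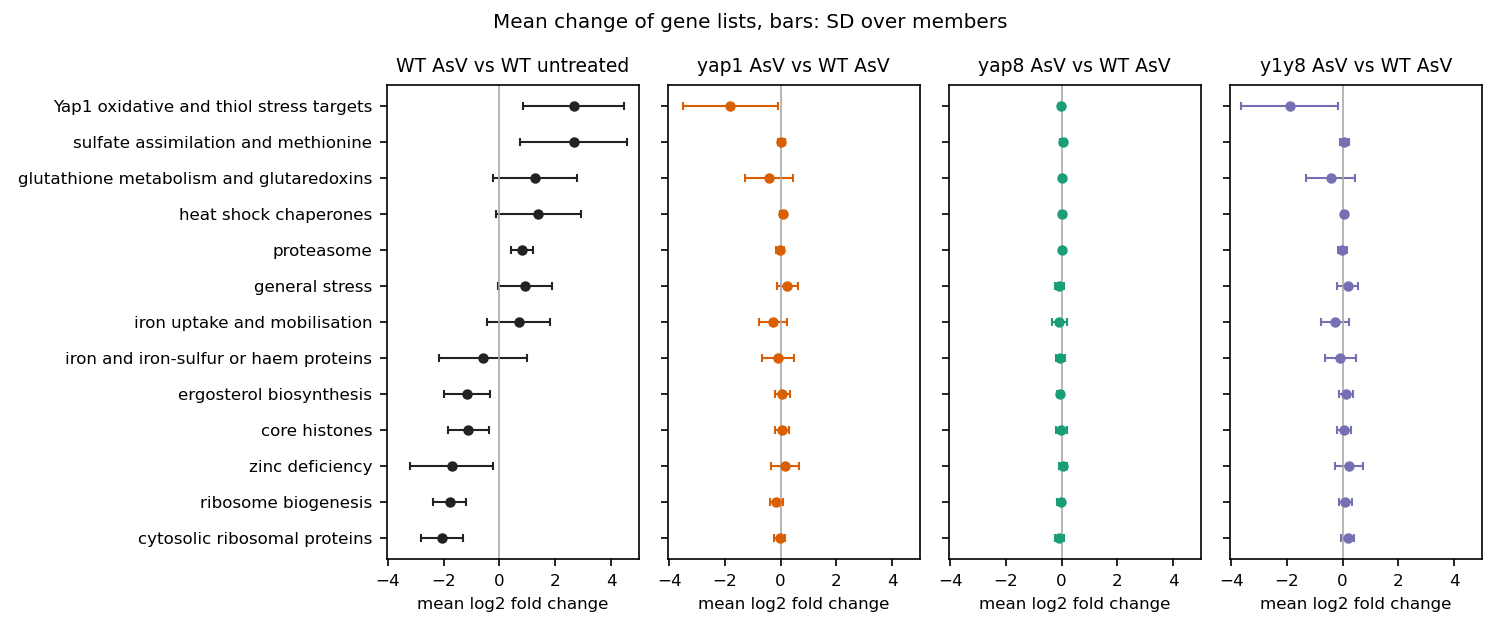
Mean log2 fold change of 13 gene lists in 4 comparisons of 3 arrays against 3. Points are means over the measured members and bars are the SD over members. Yap1 targets averaged 2.66 in treated against untreated wild type and -1.80 in yap1 against wild type, while the 13 means lay between -0.09 and 0.06 in yap8.

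The second comparison asked what loss of Yap1 changed under arsenate. Oxidoreductase, transport and thiol genes were among those lower in yap1. OSI1 was 57.9-fold lower (-5.86 ± 0.19, adjusted p = 7.51e-11), the oxidoreductase gene YLR460C was 67.9-fold lower (-6.09 ± 0.27, adjusted p = 1.89e-09) and the aryl alcohol dehydrogenase gene AAD6 was 30.3-fold lower. The multidrug transporter gene FLR1 (16.1-fold), OYE3 (15.4-fold), CIS1 (11.2-fold), the glutathione peroxidase gene GPX2 (11.1-fold), MF(ALPHA)2, an alpha factor gene (8.94-fold), and GTT2 (8.46-fold) were also lower, as were YDL218W (45.7-fold) and YDR042C (12.3-fold), which have no standard symbol. Normalized signal of OSI1 averaged 131 in untreated wild type, 10100 in treated wild type and 177 in yap1.

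The largest rises in yap1 were smaller. ANB1, the hypoxic isoform of translation factor eIF5A, was 4.38-fold higher (2.13 ± 0.23, adjusted p = 1.49e-05), followed by the iron transporter gene FET4 (1.5), INH1, an inhibitor of the mitochondrial ATPase (1.43), the reductase gene FRE7 (1.41) and HUG1, a gene induced by DNA damage (1.30). PAI3, a proteinase inhibitor (1.27), GID10 (1.2) and the polyamine transporter gene TPO3 (1.17, a call lost in a test against a change of 1.2-fold) completed the 8 largest among genes with a standard symbol. YBR090C (1.27) and YOR186W (1.26), without one, rose more than GID10 and TPO3, but the YOR186W call was lost in the test against 1.2-fold and without treated wild-type replicate 2 or yap1 replicate 1.

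Of the arsenic genes, ARR3 fell by 0.91 ± 0.16 in yap1 (adjusted p = 0.00136) and still averaged a normalized signal of 2640, against 4970 in treated wild type. ARR2 fell by 0.42 ± 0.13 (adjusted p = 0.04), a call that ended in 12 of the alternatives, 8 of which left out 1 array. ARR1 differed by -0.25 ± 0.27 (adjusted p = 0.581). FRM2 fell by 0.67 ± 0.17 (adjusted p = 0.014).

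Yap1 targets fell in 29 of 36 cases and rose in 1 (31 and 1 adjusted over the list alone), with a mean of -1.80 (adjusted p = 3.06e-36, and adjusted p = 2.47e-06 with an estimated correlation). The exception AAD10 was higher by 0.45 ± 0.13 (adjusted p = 0.0301) and its call ended in 8 of the alternatives. Glutathione genes fell in 9 of 24 cases and rose in 1 (9 and 4 adjusted over the list alone, adjusted p = 0.00428, adjusted p = 0.174 with an estimated correlation), with the glutathione transferases ECM4 (-1.97) and GTO3 (-1.74) after GTT2. Iron uptake genes fell in 7 of 31 cases and rose in 2, with the same counts adjusted over the list alone (adjusted p = 0.00428, adjusted p = 0.174 with an estimated correlation). The metal reductase gene FRE1 (-1.79), the iron-sulfur scaffold gene ISU2 (-1.5) and the mitochondrial iron carrier gene MRS4 (-1.10) fell, and HMX1 rose by 0.73.

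Single members of other lists moved without the list passing camera. With fry, adjusted p was 4.96e-05 for iron and haem proteins, 6.13e-07 for multidrug resistance, 0.0379 for copper homeostasis and 0.0308 for chaperones. It was 0.437 for ribosomal protein, 0.242 for sulfate and methionine and 0.44 for proteasome genes. The catalase gene CTA1 fell by 1.93, CCS1, the copper chaperone for superoxide dismutase, by 2.11, the reductase gene GRE2 by 2.09 and the ABC transporter gene SNQ2 by 1.11. RPL10 fell by 1.31, among 8 of 129 ribosomal protein genes that fell and 5 that rose (3 and 0 adjusted over the list alone, adjusted p = 0.121). Of 36 sulfate and methionine genes 1 rose and none fell (0 and 0 adjusted over the list alone, with 4 at an unadjusted limma p under 0.05), and the list test gave adjusted p = 0.679. Chaperones had 1 of 30 up (adjusted p = 0.211) and the proteasome 3 of 39 down (adjusted p = 0.501), with the same counts adjusted over the list alone.

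Respiratory chain genes rose in 8 of 38 cases and fell in 1 (adjusted p = 0.0128), ribosome biogenesis genes fell in 9 of 86 (adjusted p = 0.00484) and general stress genes rose in 3 of 40 and fell in 1 (adjusted p = 0.0488), each with the same counts adjusted over the list alone. None of these 3 passed with an estimated correlation (adjusted p = 0.814, adjusted p = 0.823 and adjusted p = 0.823). The respiratory and biogenesis calls ended without yap1 replicate 1, the biogenesis call also without treated wild-type replicate 2, and the general stress call in 10 of 15 fits that left out 1 array.

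In total 1059 genes differed between yap1 and wild type, 537 higher and 522 lower, with 16 and 133 of them by at least 2-fold. The split moved when 1 array was left out, with 357 higher and 452 lower without treated wild-type replicate 1, 309 and 446 without replicate 2, 341 and 440 without replicate 3, and 343 and 456 without yap1 replicate 3. Array weights raised the count to 2046, with 1266 higher and 780 lower, and a test against a change of 1.2-fold lowered it to 295, with 40 higher and 255 lower.

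The genes lower in yap1 were compared with those raised by arsenate in wild type. No mutant was measured without arsenate, so a lower level before treatment and a smaller rise cannot be told apart. Mean normalized signal of YLR460C was 128 in untreated wild type and 32 in treated yap1, while that of OSI1 was 131 and 177. Of the 522 lower genes 334 (64.0%) were among the arsenate-raised genes, where independent calls would give 218.9, and 99 passed 2-fold in both. In the mirror case 177 of the 537 higher genes were among the arsenate-lowered genes, where independent calls would give 210.7. The comparisons share the 3 treated wild-type arrays, which pulls their changes in opposite directions. Simulated groups without change that shared arrays gave an overlap of 0, since almost no gene is called where none changes. That value therefore does not show how much the shared arrays add to the overlap among genes that do change. Across genes the changes correlated at -0.177, weaker than the -0.498 of the simulated groups, while their covariance was -0.0922 against -0.0093 simulated. A comparison that shares no array, y1y8 against yap8, put 384 of its 557 lower genes among the arsenate-raised genes, where independent calls would give 233.5, and 304 of its 515 higher genes among the arsenate-lowered genes, where independent calls would give 202.1. These changes correlated at -0.344 against -0.003 in simulated groups.

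The third comparison asked what loss of Yap8 changed under arsenate. Few genes moved. Beside ARR1 itself, ARR2 fell 5.74-fold (-2.52 ± 0.13, adjusted p = 1.7e-07) and ARR3 fell 3.40-fold (-1.76 ± 0.16, adjusted p = 0.000116). ARR3 still averaged a normalized signal of 1480 in yap8, against 65.5 in untreated wild type. The genes ARR1, ARR2 and ARR3 are neighbours in this order in the gene table of assembly R64.

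Outside the arsenic genes the cell wall protein genes TOS6 and SVS1 fell by 1.47 ± 0.17 (adjusted p = 0.00128) and 1.25 ± 0.13 (adjusted p = 0.000353). URA3, a uracil synthesis gene and common plasmid marker, was higher by 0.53 ± 0.09 (adjusted p = 0.0441), and YKR005C, named because it completes the 7, was higher by 0.39 (adjusted p = 0.043). Neither rise passed with median centring, which gave 0 higher and 6 lower genes, or with quantile normalization over the yeast probe sets alone, which gave 0 and 5. The URA3 call ended in 17 of the alternatives and the YKR005C call in 20. FRM2 differed by -0.14 and YAP1 by 0.02 ± 0.13 (adjusted p = 1).

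The 7 genes that passed in limma were 2 higher and 5 lower, and 368 genes had an unadjusted p under 0.05. None of the 36 Yap1 targets passed, and none had an unadjusted p under 0.05. Ribosomal protein genes shifted slightly as a list, with a mean of -0.09 (adjusted p = 6.7e-09, but adjusted p = 0.51 with an estimated correlation), while none of the 129 passed alone (3 lower adjusted over the list alone, 28 at an unadjusted p under 0.05). Ergosterol genes had a mean of -0.07 (adjusted p = 0.00727, adjusted p = 0.51 with an estimated correlation) with none of 25 past, also adjusted over the list alone, and 5 at an unadjusted p under 0.05. That list call ended without treated wild-type replicate 2. Array weights raised the count of genes from 7 to 18, with 4 higher and 14 lower, and without y1y8 replicate 3 there were 2 higher and 8 lower genes. With eBayes with trend and robust prior there were 10 genes, 1 higher and 9 lower, of which 6 were among the 7.

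The fourth comparison asked what loss of both regulators changed under arsenate. ARR2 and ARR3 were lower here than in either single mutant. ARR2 was 165-fold lower than in wild type (-7.37 ± 0.13, adjusted p = 3.38e-13) and ARR3 67.0-fold lower (-6.07 ± 0.16, adjusted p = 8.08e-12), with ARR3 at a mean normalized signal of 75.4 against 65.5 in untreated wild type. FRM2 was 19.6-fold lower (-4.29 ± 0.17, adjusted p = 5.2e-10). YLR460C (-6.19), OSI1 (-5.59), YDL218W (-5.30), AAD6 (-5.01), FLR1 (-4.01) and OYE3 (-4.00) were lower by amounts close to those in yap1. The largest rises were ANB1 (2.01), FET4 (1.62), the hexose transporter gene HXT5 (1.57), the riboflavin transporter gene MCH5 (1.51), HUG1 and PAI3 (1.48 each), INH1 (1.39) and AMF1 (1.38).

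Yap1 targets fell in 29 of 36 cases (31 adjusted over the list alone, with 1 higher) with a mean of -1.90 (adjusted p = 2.57e-36, and adjusted p = 2.45e-06 with an estimated correlation). Glutathione genes fell in 8 of 24 cases and rose in 1, with the same counts adjusted over the list alone (adjusted p = 0.00466, adjusted p = 0.199 with an estimated correlation), and iron uptake genes fell in 10 of 31 and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 0.00197, adjusted p = 0.187 with an estimated correlation). Examples were GTT2 (-3.15), ECM4 (-2.09), FRE1 (-1.66) and ISU2 (-1.39). MF(ALPHA)2 fell by 3.56. Ribosomal protein genes rose in 34 of 129 cases and fell in 2 (48 and 3 adjusted over the list alone), with RPS19A at 0.99 and RPL10 at -1.21 (adjusted p = 1.51e-05, adjusted p = 0.624 with an estimated correlation). Respiratory chain genes rose in 7 of 38 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00615, adjusted p = 0.624 with an estimated correlation), a call that ended without y1y8 replicate 3. Sulfate and methionine genes had 2 of 36 up and none down, with the same counts adjusted over the list alone (adjusted p = 0.41). URA3 was higher by 0.78 ± 0.09 (adjusted p = 2.87e-05).

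In total 1115 genes differed between y1y8 and wild type, 563 higher and 552 lower, with 26 and 139 of them by at least 2-fold. The split was 357 higher and 446 lower without treated wild-type replicate 1, and 367 and 473 without replicate 3. Array weights raised the count to 1942, with 1158 higher and 784 lower, and a test against 1.2-fold lowered it to 342, with 60 higher and 282 lower. Of the lower genes 454 were also lower in yap1, where independent calls would give 51.6. These comparisons share the 3 treated wild-type arrays, and the changes correlated at 0.868 across genes against 0.499 in simulated groups without change.

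The mutants were next compared directly, and ARR2 and ARR3 fell on loss of either regulator in cells already lacking the other. Loss of Yap8 in cells already lacking Yap1 lowered 5 genes and raised none in limma, with 380 at an unadjusted p under 0.05. By its bound ARR1 was 357-fold lower in y1y8 than in yap1. ARR2 fell by 6.95 ± 0.13 (adjusted p = 7.51e-13), ARR3 by 5.15 ± 0.16 (adjusted p = 1.76e-10) and FRM2 fell by 3.62 ± 0.17 (12.3-fold, adjusted p = 2.15e-08). KEL2, a kelch-repeat protein gene named because it completes the 5, fell by 0.56 (adjusted p = 0.0198), and 4 of the 5 genes, without it, passed with median centring. Ribosomal protein genes had a mean of 0.21 (adjusted p = 2.77e-43, but adjusted p = 0.179 with an estimated correlation), with none of 129 past over all genes, 56 higher adjusted over the list alone and 74 at an unadjusted p under 0.05. Ribosome biogenesis genes had a mean of 0.25 (adjusted p = 5.12e-19, adjusted p = 0.842 with an estimated correlation), with none of 86 past, also adjusted over the list alone, and 24 at an unadjusted p under 0.05. Phosphate starvation genes had a mean of 0.16 (adjusted p = 0.00632, adjusted p = 0.546 with an estimated correlation), with none of 23 past, 2 higher adjusted over the list alone and 3 at an unadjusted p under 0.05, and the list call ended without y1y8 replicate 3. With median centring 4 more lists passed, all lower, namely chaperones (-0.12, adjusted p = 0.00268), Gcn4 targets (-0.12, adjusted p = 0.00122), general stress genes (-0.13, adjusted p = 0.0317) and the proteasome (-0.06, adjusted p = 0.0104). The Gcn4 call also came without yap1 replicate 1 and without y1y8 replicate 1 or 2, and the general stress call without yap1 replicate 2. Respiratory chain genes passed without yap1 replicate 1, and ergosterol genes without y1y8 replicate 1. The absence of rises did not hold with array weights, which gave 110 genes, 67 higher and 43 lower. Adding 16 before log2 gave 6 genes, 1 higher and 5 lower, and so did eBayes with trend and robust prior. The count was 8, with 1 higher and 7 lower, without wild-type untreated replicate 2, and 9, with 1 higher and 8 lower, without yap1 replicate 2. There were 2 higher genes without treated wild-type replicate 1 and 1 without yap1 replicate 1.

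Loss of Yap1 in cells already lacking Yap8 changed 1072 genes, 515 higher and 557 lower. The split was 336 higher and 477 lower without yap8 replicate 1, 299 and 479 without yap8 replicate 3, 338 and 483 without y1y8 replicate 2, and 341 and 482 with all probe sets. YLR460C fell by 6.19, OSI1 fell by 5.60, YDL218W fell by 5.35 and AAD6 fell by 5.04, and ARR2 and ARR3 fell by 4.85 and 4.30. Mean log2 signal of FRM2 was 12.88 in yap8 and 8.74 in y1y8. ANB1 (1.96), RPL41A (1.94), INH1 (1.45) and FET4 (1.37) rose, although the RPL41A call (adjusted p = 0.0247) ended in 6 of the alternatives. Yap1 targets fell in 29 of 36 cases and rose in 1 (30 and 1 adjusted over the list alone). Ribosomal protein genes rose in 53 of 129 cases and fell in 3 (85 and 3 adjusted over the list alone, adjusted p = 4.95e-13, but adjusted p = 0.362 with an estimated correlation). Of the 8 lists that passed, 1, the Yap1 targets, held with an estimated correlation. With median centring the calls of iron uptake, general stress and cell wall genes were lost and that of hexose transport was gained. The call of iron uptake genes also ended without yap8 replicate 1, that of general stress genes without yap8 replicate 2 or y1y8 replicate 3 and that of ergosterol genes without y1y8 replicate 3. Array weights gave a count of 1664, with 953 higher and 711 lower, and a test against 1.2-fold 331, with 52 higher and 279 lower. Of the 557 lower genes 446 were also lower in yap1 against wild type, a comparison with no array in common, where independent calls would give 52.0. The changes correlated at 0.888 across genes, against 0.004 in simulated groups.

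**Figure D3:**
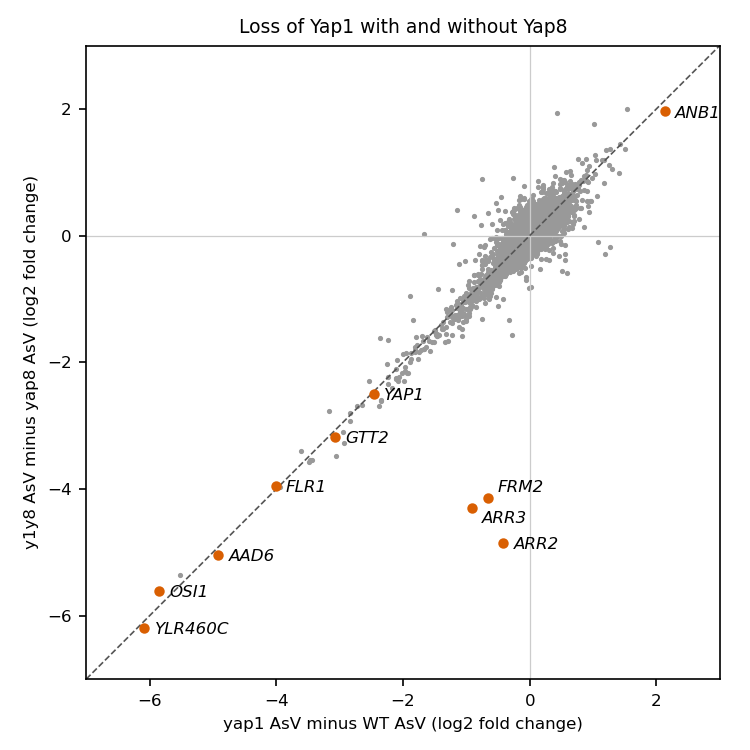
Log2 fold change of 5588 genes after loss of Yap1 with Yap8 present (horizontal axis) and without it (vertical axis), from comparisons with no array in common. Each point is a gene, the dashed line marks equal change and 10 genes are named. ARR2, ARR3 and FRM2 lie far below the line.

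The single mutants differed from each other in 1218 genes, 623 higher and 595 lower in yap1. The split was 393 higher and 481 lower without yap1 replicate 1, 395 and 493 without yap1 replicate 3, 368 and 488 without yap8 replicate 3, and 406 and 500 with all probe sets. YLR460C (-6.08), OSI1 (-5.87), YDL218W (-5.57), AAD6 (-4.95), FLR1 (-3.96) and OYE3 (-3.90) were lower in yap1. ARR1 was 330-fold higher by its bound, and ARR2 (2.10), ARR3 (0.85) and ANB1 (2.08) were higher. RPL41A was higher by 1.64 (adjusted p = 0.0496), a call that ended in 17 of the alternatives. LEU2, a leucine synthesis gene and common plasmid marker, was higher by 0.95 ± 0.20 in yap1 than in yap8 (adjusted p = 0.0042). Of the 6 lists that passed, 1, the Yap1 targets (adjusted p = 4.27e-06), held with an estimated correlation. Without yap1 replicate 1 the calls of general stress, respiratory chain and ribosome biogenesis genes ended, without yap1 replicate 2 that of cell wall genes, and without yap1 replicate 3 or yap8 replicate 2 or 3 those of ribosome biogenesis and cell wall genes. Array weights gave a count of 2012, with 1199 higher and 813 lower, and a test against 1.2-fold 355, with 72 higher and 283 lower.

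The last comparison tested whether the loss of both regulators differed from the sum of the single losses on the log2 scale. It did so for 3 genes in limma, all lower than the sum, and 237 genes had an unadjusted p under 0.05. ARR2 was lower by -4.43 ± 0.19 (adjusted p = 2.15e-08), FRM2 by -3.48 ± 0.24 (adjusted p = 3.65e-06) and ARR3 by -3.39 ± 0.23 (adjusted p = 3.65e-06). Mean normalized signal of FRM2 was 104 in untreated and 8360 in treated wild type, 5280 in yap1, 7560 in yap8 and 439 in y1y8. That of ARR2 was 2180, 4360, 3260, 771 and 26.4 in the same order. HBN1, the neighbour of FRM2 in the gene table and named here after its values were seen, averaged 744, 8610, 4420, 8540 and 4470. Its departure from the sum was 0.03. The 3 lists that passed went the other way, above the sum. Ribosomal protein genes had a mean of 0.29 (adjusted p = 2.12e-61, but adjusted p = 0.06 with an estimated correlation), with none of 129 past over all genes, 38 higher adjusted over the list alone and 65 at an unadjusted p under 0.05. Ribosome biogenesis genes had a mean of 0.28 (adjusted p = 2.79e-16, but adjusted p = 0.622 with an estimated correlation), with 10 of 86 at an unadjusted p under 0.05, and ergosterol genes a mean of 0.14 (adjusted p = 2.57e-05, but adjusted p = 0.564 with an estimated correlation), with 4 of 25. In both lists no gene passed over all genes or adjusted over the list alone. Array weights gave 5 genes, 1 higher and 4 lower, and the fit without yap1 replicate 1 gave 1 higher and 3 lower.

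The submitters deposited their own lists for 3 of these comparisons, restricted to fold changes with a lower bound of 1.2 or more. They held 3702 genes for arsenate in wild type, 553 for yap1 and 25 for yap8. Of the listed genes that could be matched, 99.5%, 99.6% and 100% had the same direction here, and 97.5%, 89.6% and 20% also passed the adjusted p of 0.05. At 0.01 the shares were 95.2%, 76.4% and 16%. These are the same arrays, so the shares compare methods and not experiments.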

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

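The tests on a linear scale and the tests of the remaining YAP1 signal were chosen after those results were seen, while the counts of other assignments and the test of bright probe sets were chosen before.

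The loss of both regulators differed from the sum of the single losses, by a test of the difference itself, for ARR2 (-4.43), FRM2 (-3.48) and ARR3 (-3.39). Losses that add on the linear scale predict for FRM2 a signal of 4490 in y1y8, and the observed 439 lay -12.4 SE from it if signal is proportional to RNA. Saturation of its probe set would under-read the wild-type signal and raise that sum. It stays open, since 46 genes were brighter and each probe set has its own ceiling, so linear addition and saturation cannot be told apart from a combined loss for FRM2. For ARR2 and ARR3 the linear sums were -329 and -846, below any signal an array can give, so that an additive and a combined loss cannot be told apart on that scale. Shared control of these genes by both regulators stays open as a candidate explanation that these arrays did not test.

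Among 100 assignments of the 12 treated arrays that kept each array among those with or without Yap1, 12, the real one included, gave at least 3 genes, and the highest other gave 16. Of the 11 others, 10 kept the arrays of yap1 and y1y8 apart and called ARR2, ARR3 and FRM2 themselves. Such assignments hold the same contrast and were 11 of the 100, the real one included, so the share was too high from the start to fall under 0.05 for a difference between y1y8 and yap1. Of the 89 that mixed those arrays, 1 gave as many genes. It set yap1 replicate 2 and y1y8 replicates 1 and 2 against the other 3 arrays without Yap1 and exchanged replicate 3 of treated wild type with replicate 3 of yap8, and none of its 16 genes was ARR2, ARR3 or FRM2. Whether a count several times the real one reflects a structure among the arrays was not tested. Deviations from the group means correlated at 0.408 between replicate 2 of yap1 and of y1y8, which this split kept together. They correlated at 0.339 between yap1 replicate 1 and y1y8 replicate 3, also together. Between arrays set apart they correlated at -0.398 for yap1 replicate 2 and y1y8 replicate 3, but at 0.111 for yap1 replicate 3 and y1y8 replicate 1. These pairs were picked after the split was seen, and deviations within a group are not independent, so they do not establish a structure. The next highest of the 89 gave 1.

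The YAP1 probe set kept 18.2% of the signal of treated wild type in yap1 and 18.0% in y1y8. Wild-type cells in the mutant cultures at that share would hold every other gene at or above it, and 8 genes lay under 0.5 of that share in both mutants, among them YLR460C at 1.53% and 1.43% and OSI1 at 1.76% and 2.12%. That argues against wild-type cells as the whole source. A part of the YAP1 transcript left in the mutants, or RNA of other genes on its probes, predicts a like signal in both, and the ratio of the signals was 1.01, consistent with either. Which of these holds was not tested.

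Probe sets with no gene name entered the text only in the counts with all probe sets. Of the 3330, 277 reached the limit for dim probe sets of 2.79 in mean log2 value, and the rest lay below it. Which species they belong to was not tested. Of 3330 such probe sets 222 changed in treated against untreated wild type, with 78 higher and 102 lower by at least 2-fold, and 72 were called present on all arrays.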

How the results depend on the processing

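Gene names from the platform annotation alone were an alternative chosen after the data were seen, and all other alternatives were chosen before. The series matrix gave identical values, so it moved nothing. Of 11924 values of 442 named gene results under the alternatives, 11298 kept direction and side of the threshold, 607 lost the call, 18 gained one and 1 reversed. Of 4368 values of 175 list results the counts were 4251, 75, 41 and 1. In these totals 31 gene and 106 list values that changed sign without passing in either setting count as kept.

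Array weights gave 2046 genes for yap1 against wild type, 18 for yap8, 1942 for y1y8, 110 for y1y8 against yap1, 1664 for y1y8 against yap8, 2012 for yap1 against yap8 and 5 for the departure from the sum. The cause was not tested. A test against a fold of 1.2 gave 295, 342, 331 and 355 genes for yap1, y1y8, y1y8 against yap8 and yap1 against yap8, and ended 139 of 426 gene calls, since it asks for a larger change. Camera with an estimated correlation kept 5 of 27 list calls. Estimated correlations were 0.73 for ribosome biogenesis, 0.686 for general stress and 0.31 for ribosomal protein genes, above the preset 0.01. That of Yap1 targets was 0.007, yet their camera adjusted p in wild type went from 3.98e-12 to 0.000487. A larger correlation thus does not account for every weaker value, and the share due to it was not tested. Requiring 2-fold lowered the overlap of arsenate-raised and yap1-lowered genes from 334 to 99, since it calls fewer genes.

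Under median centring PFK1 in arsenate-treated wild type turned from 0.19 to -0.33 (adjusted p = 0.00716), and the proteasome list in y1y8 against yap1 from 0.02 to -0.06 (adjusted p = 0.0104). The cause was not tested.

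Leaving out 1 array gave 4 to 9 genes for y1y8 against yap1, where the highest came without yap1 replicate 2 and a count of 8 without wild-type untreated replicate 2. The other ranges were 4355 to 4568 for arsenate, 755 to 1319 for yap1, 5 to 10 for yap8, 803 to 1382 for y1y8, 778 to 1288 for y1y8 against yap8, 856 to 1434 for yap1 against yap8, 3 to 4 for the departure from the sum and 24 to 29 for list calls. Wild-type untreated replicate 2 deviated most from its group mean (SD 0.23, next y1y8 replicate 3 at 0.186), and all arrays share an estimate of the spread. Without it came the highest counts for yap1, y1y8, y1y8 against yap8 and yap1 against yap8. For arsenate and yap8 the highest came without y1y8 replicate 3. Why the counts moved was not examined further. The cause was not tested.

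With replicate number as a block the counts were 4521, 993, 5, 1033, 4, 1004, 1145 and 3 in the order of the comparisons. The numbers do not show a pairing, since 6 of 30 pairs with the same number correlated above 0.1 and the median was 0.014. The 60 pairs with different numbers had a median of 0.008. Single pairs among them reached 0.357 (treated wild-type replicate 2 and y1y8 replicate 3) and -0.398 (yap1 replicate 2 and y1y8 replicate 3). Leaving out dim probe sets kept 5568 of 5588 genes, too small a change to show what signal over background limits in the rest. It limited the fold of ARR1 in yap8 and y1y8, which is given as a bound.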

Other observations

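The cell cycle and hypoxia lists were chosen after the data were seen, as were the tests of both hypotheses, while the counts of other splits were chosen before.

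Adjusted p of these lists is given together with the 25 fixed lists tested. Cell cycle genes were lower in treated than in untreated wild-type cells. Of 25 genes of the G1/S transition 22 fell and 1 rose, with a mean of -1.91 (camera adjusted p = 1.76e-07, adjusted p = 0.0194 with an estimated correlation), and the ribonucleotide reductase gene RNR1 was at -4.07. Of 17 G2/M genes 12 fell and 1 rose (adjusted p = 0.00955, adjusted p = 0.45 with an estimated correlation). In yap8 against treated wild type the means were -0.13 for G1/S and -0.14 for G2/M (adjusted p = 0.0103 and adjusted p = 0.00146, but adjusted p = 0.48 for each with an estimated correlation), with none of either list past in limma, 3 and 0 lower adjusted over the list alone, and 4 and 1 at an unadjusted p under 0.05.

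A hypothesis from the falls of HO, CLB6, PCL1 and RNR1 was that G1/S genes were lower as a set. HO was not in the list of 25, and without the other 3 the remaining 22 members had 19 lower and 1 higher with a mean of -1.64 (adjusted p = 0.0208 with an estimated correlation), consistent with it. Time and arsenate changed together, so which of them goes with this fall cannot be told from these arrays.

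A hypothesis from the rises of ANB1, FET4 and TIR1 in yap1 was that genes repressed by haem and oxygen were higher there as a set. The other 21 members had 4 higher and 4 lower with a mean of -0.19 and a median of 0 (adjusted p = 0.82 with an estimated correlation). Members went both ways with an SD of 0.79, and these 21 showed no rise as a set. A rise of single members, or of a set small beside this spread, is not excluded. In treated against untreated wild type 15 of the 24 genes fell and 5 rose (adjusted p = 0.0308, adjusted p = 0.194 with an estimated correlation). ROX1, a repressor of hypoxic genes, had a mean normalized signal of 1190 in treated wild type, 515 in yap1 and 695 in y1y8, while ANB1 had 28.7, 126 and 122. A link between ROX1 and ANB1 was not tested.

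For the 7 comparisons of 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many genes in each comparison. The real counts and the highest of the other splits were 4536 and 0 for arsenate in wild type, 1059 and 1 for yap1, 7 and 0 for yap8, 1115 and 0 for y1y8, 5 and 2 for y1y8 against yap1, 1072 and 1 for y1y8 against yap8, and 1218 and 0 for yap1 against yap8. The other splits mix arrays of both groups, so a difference between the groups enters their spread and lowers their counts. These low counts therefore lend the real ones no support.

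Plasmid markers differed between groups. URA3 fell by 0.57 and LEU2 by 0.60 in treated against untreated wild type (adjusted p = 5.29e-05 and adjusted p = 0.0142). URA3 was higher in y1y8 than in treated wild type by 0.78, and LEU2 was higher in y1y8 than in yap8 by 0.84. The first LEU2 call ended without wild-type untreated replicate 2 and in the test against a fold of 1.2, and the last in that test and in a fit of only the groups compared.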
